A study of Rattus norvegicus with 17 samples.

How the data were processed

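The series measured gene expression in colon mucosa of 17 HLA-B27 transgenic rats, 8 fed a high and 9 a low calcium diet, with 1 array per rat. Per the labels' protocols, mucosal scrapings were homogenised under liquid nitrogen, RNA was isolated with TRIzol and columns, amplified and labelled, with each rat in Cy5 and a pool of all animals in Cy3 on every array. No array had the dyes swapped, so a dye effect is shared by both groups and leaves their difference. The rats were taken as separate animals from their labels, and groups came from the sample titles.

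The deposited scanner files hold spot intensities (mean and background signals of both dyes, and flags) written by Agilent Feature Extraction 9.5.1.1, per the file headers; the submitters' processing notes name version 9.5. The deposited series matrix holds log2 values for 28213 of 45018 features, and what the authors did to make them is not given in the sources used here. Set against the scanner values, it followed the log2 ratio of Cy5 to Cy3 signals without background subtraction (r = 0.979 after centring genes and arrays, across genes and arrays, which are not independent replicates). Its array medians were all 8.76, so arrays had been brought to 1 median, and the offset of the scale stays unknown. It served as an alternative only, and 0 columns of it were left unused.

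From the intensities, background was corrected by normexp with an offset of 50, and each array was normalised by loess with control spots and spots flagged as outliers at weight 0, in limma 3.58.1 under R 4.3.3. Flagged spots were then set to missing, control spots were dropped, and the spots of a probe were averaged, which took 43379 spots to 41012 probes. A probe was tested if it lay well above background in Cy5 on at least 8 arrays, whatever their group, which left 27101 probes. Median Cy5 signal ran from 146.8 to 180.8 per array, over a median background of 43.5 to 53.5, and at most 3 spots per array were saturated. Normalising each array to its own centre means that a change shared by most genes would not be seen.

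Probes carry the gene names of the array's design. Those names were updated through the GRCr8 RefSeq table by accession for 10735 probes, by symbol for 5577 and by synonym for 3730, and 20970 kept the array's name. A gene was represented by its brightest probe; of 3200 genes with several probes 1143 had probes that differed in sign. The member entered as neutrophil elastase was matched through an old name to a probe whose accession now names Cela2a, a pancreatic elastase, and is kept as fixed. No coordinates are given, because no genome was used here.

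Groups were compared with limma's lmFit and eBayes, two-sided, without covariates, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The 33 gene lists were tested with camera at a preset correlation of 0.01, where missing values were set to the probe's mean, and adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of each list's mean per rat over all 24310 assignments of 8 of the 17 rats. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the 15 largest rises and falls among genes past the threshold; where fewer pass, the 5 with the smallest p in each direction, given as values that did not pass, leaving out names that are accessions or uncharacterised loci. It also names up to 5 members with the smallest unadjusted p in each list that passed camera and in 12 lists described in any case; other lists are given by count. The values of 1 gene under this rule are not reported here, and it was left out of the search for single rats far from their group.

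The fit was tested on simulated arrays made from the real probe means and spreads, for 8 against 9 arrays and 26968 probes. Of 67 probes changed by 0.5 on the log2 scale 97.0% were called, as were 100% of those changed by 1 or 2, with 11 unchanged probes called. These simulated probes vary independently, which real genes do not. The changed probes were drawn at random, and the median SE of a difference over all real probes was 0.057. The shares called therefore do not hold for genes that vary more between rats. Mmp13 and Mmp10, given below, differed by more than 1 and did not pass over all genes. Alternatives to the background correction, normalisation, filter, variance model, batch, probe rule and set test, and leaving out each rat in turn, were run for the counts past the threshold, the gene lists and the named genes, wherever a gene or list could be tested. The splits of the rats, the diet score, the contrast of cell type lists and the relations within a diet were computed with the reported settings only.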

Results

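Colon mucosa was compared between HLA-B27 transgenic rats fed a diet high or low in calcium. These rats carry the human HLA-B27 and β2-microglobulin transgenes and develop colitis, and the question the series poses is how dietary calcium affects that colitis. All animals were females of an inbred Fischer background, 8 to 10 weeks old at the start. The high calcium diet held 120 mmol calcium per kg and was eaten by 8 rats; the low calcium diet held 30 mmol per kg and was eaten by 9 rats. RNA from mucosal scrapings of each rat was hybridised to its own 2-colour array, with the rat in Cy5 and a pool of all animals in Cy3, so that each value is a log2 ratio of one rat to that pool. Between 60.0% and 72.0% of the probes lay well above background in the rat's channel on an array, and the number of rats, not of spots, limits the precision. Differences below are high minus low calcium on the log2 scale, with the standard error of limma's fit over 8 and 9 rats (7 and 9 for Pyy).

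Matrix-degrading proteases were lower in the rats fed high calcium. Mmp13, a collagenase, differed by -1.94 ± 0.34 (SE), which is 3.82-fold lower, and Mmp10, a stromelysin, by -1.63 ± 0.30, which is 3.09-fold lower. Mmp9, a gelatinase that neutrophils also carry, differed by -1.01 ± 0.21, Mmp7 by -0.44 ± 0.10 and Plau, the urokinase plasminogen activator, by -0.41 ± 0.09. Of the 21 measured members of this list 18 were lower and 3 higher; 12 passed the threshold adjusted over the list alone, all of them lower, and 0 passed it over all genes tested. With median centring of the arrays in place of loess 6 passed over the list alone. The mean of the list was -0.29 ± 0.21 (SD, n = 8) at high and 0.13 ± 0.15 (SD, n = 9) at low calcium. By this mean 7 of the 8 high calcium rats lay below every low calcium rat. The list fell against all other genes (camera adjusted p = 2.05e-16, and adjusted p = 0.037 with an estimated correlation), and its mean per rat differed by an exact two-sided permutation test (p = 0.00082, adjusted p = 0.022 over 33 lists).

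Genes of the extracellular matrix were lower at high calcium as well. The small proteoglycans decorin (Dcn, -1.03 ± 0.22), lumican (Lum, -0.59 ± 0.13) and biglycan (Bgn, -0.50 ± 0.12), the basement membrane glycoprotein nidogen (Nid1, -0.65 ± 0.15) and the collagen chain Col1a1 (-0.53 ± 0.12) had the smallest p among them. Of the 27 measured members of the matrix structure list 25 were lower, and 20 passed adjusted over the list alone, against 0 over all genes. The list mean was -0.20 ± 0.22 (SD, n = 8) at high and 0.15 ± 0.15 (SD, n = 9) at low calcium. The fall passed camera (adjusted p = 2.97e-24), camera with an estimated correlation (adjusted p = 0.037) and the exact permutation test of the means (adjusted p = 0.025). Fibroblast and mesenchymal markers, 5 of which are also in the matrix list, followed with 19 of 20 members lower and 12 past adjusted over the list alone. Among them were the platelet-derived growth factor receptors Pdgfra (-0.49 ± 0.11) and Pdgfrb (-0.39 ± 0.10). That list passed camera (adjusted p = 1.70e-16) and the exact permutation test (adjusted p = 0.031), but not camera with an estimated correlation (adjusted p = 0.074). With median centring in place of loess, 0 matrix and 0 fibroblast members passed adjusted over the list alone. There the list medians were -0.29 and -0.34, against -0.32 and -0.38 with loess, while the median residual SD of a probe was 0.27 against 0.12. Smooth muscle markers had a median difference of -0.05 and did not pass (camera adjusted p = 0.056). They were called as lower in 11 of 31 other camera settings, with a smallest adjusted p of 0.010. Within that list 10 of 17 members were lower and 2 passed adjusted over the list alone, Tpm2 (-0.40 ± 0.10) and Csrp1 (-0.24 ± 0.06); this count was 4 without rat 9 or rat 15, 6 with array weights and 0 with median centring. With the smooth muscle mean of each rat as a covariate, the difference of the matrix list mean was -0.24 ± 0.06 (SE), against -0.35 ± 0.09 without it, and that of the fibroblast list was -0.20 ± 0.05, against -0.34 ± 0.10.

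**Figure D1:**
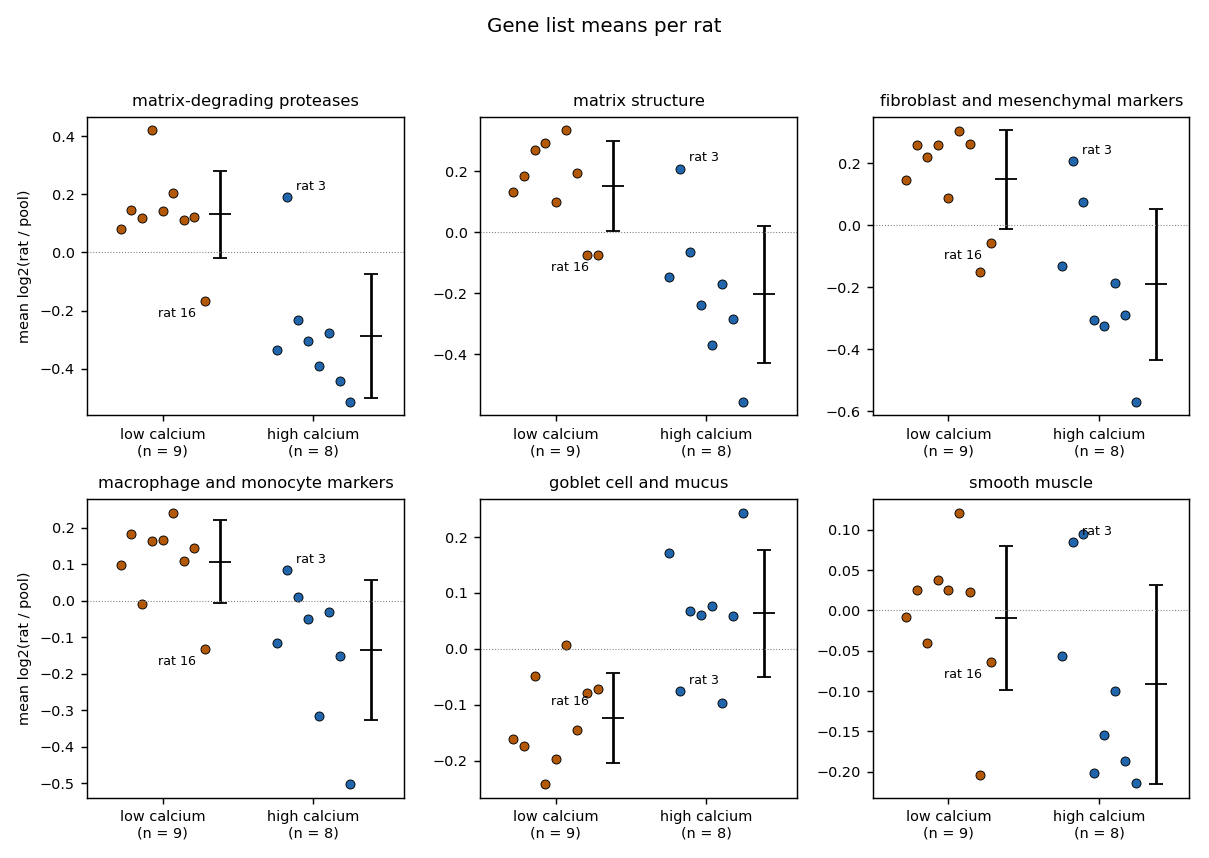
Mean log2 ratio to the common pool over the members of 6 gene lists (vertical axes), 1 point per rat, for 9 low and 8 high calcium rats; bars give the mean ± SD of each group. In the protease panel 7 of the 8 high calcium rats lie below all low calcium rats, and rat 3 (0.19) does not.

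Macrophage and monocyte markers were lower in the high calcium group. Trem2 and Gpnmb, both expressed by lipid-handling and scavenging macrophages, differed by -0.94 ± 0.21 and -0.72 ± 0.16, and Cd68 by -0.35 ± 0.10. Of 23 measured members 21 were lower and 11 passed adjusted over the list alone, with 0 over all genes. With median centring 0 passed over the list alone, and with the smooth muscle covariate 2 did. The list median was -0.15 with median centring, against -0.13 as reported. All 8 high calcium rats lay below the mean of the low calcium rats, and 3 of them lay below every low calcium rat. The list passed camera (adjusted p = 8.55e-12) and the exact permutation test (adjusted p = 0.031), but not camera with an estimated correlation (adjusted p = 0.11). Pla2g7, a secreted phospholipase made by macrophages, had the smallest p of all named genes (-0.38 ± 0.06, limma adjusted p = 0.098).

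Neutrophil markers had a median difference of -0.15, with 13 of 17 members lower and 6 past adjusted over the list alone. The smallest p values there belonged to Mmp9, the integrin subunit Itgam (-0.26 ± 0.07) and Ncf1, a subunit of the phagocyte oxidase (-0.39 ± 0.10). Complement and acute phase genes had a median of -0.13, with 9 of 25 members past adjusted over the list alone, among them C1s (-0.43 ± 0.12), C1r (-0.38 ± 0.11) and tissue factor (F3, -0.53 ± 0.16). Endothelial and adhesion genes had a median of -0.13, with 3 of 15 members past, which were Vwf (-0.28 ± 0.08), the mucosal addressin Madcam1 (-0.34 ± 0.11) and Icam2 (-0.15 ± 0.05). Protease inhibitors had a median of -0.07 with 4 of 16 members past, Serping1 (-0.33 ± 0.10), Serpine2 (-0.37 ± 0.12), Slpi (-0.31 ± 0.11) and Reck (-0.15 ± 0.05). These 4 lists passed camera as lower (adjusted p = 3.37e-06 for the first 3 and 0.0012 for the inhibitors). None passed with an estimated correlation (adjusted p = 0.17, 0.11, 0.15 and 0.14 in the order given), and none passed the exact permutation test after adjustment (adjusted p = 0.064 for each). With the smooth muscle covariate the medians of the first 3 were -0.07, -0.06 and -0.04. The neutrophil, endothelial and inhibitor medians were -0.36, -0.24 and -0.15 with the scanner software's processed signals. The counts of members past in these 4 lists moved with single rats. Neutrophil markers had 3 without rat 4, 13 or 18, and complement genes had 5 without rat 4, 6 or 17 and 4 without rat 18. Endothelial genes had 0 without rat 4, 6, 10 or 18, 1 without rat 5 or 17, and 6 without rat 3 or 15. Inhibitors had 0 without rat 1, 2, 4, 5, 6, 13, 17 or 18, 1 without rat 9 and 2 without rat 10. With median centring 2 neutrophil markers and 0 members of the other lists passed, and with the smooth muscle covariate 3 and 0. With the slide as a block 2 of the inhibitors passed.

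Inflammatory cytokines and chemokines had 26 of 32 members lower, with a median of -0.11, but 0 members past adjusted over the list alone (4 without rat 9). The smallest p values were those of Il1rn (-0.30 ± 0.11), Ptgs2 (-0.25 ± 0.10) and Ccl2 (-0.46 ± 0.20). The list passed camera (adjusted p = 1.14e-05), but neither camera with an estimated correlation (adjusted p = 0.32) nor the exact permutation test (adjusted p = 0.21). Genes of the unfolded protein response had a median of -0.05 (camera adjusted p = 0.0035, adjusted p = 0.47 with an estimated correlation), and 0 of 26 members passed adjusted over the list alone. The list was called in 28 of 32 other camera settings, and not without rat 17 (median -0.03, adjusted p = 0.070) or with array weights (adjusted p = 0.053). The sign of its median turned with median centring (0.0011) and with the smooth muscle covariate (0.0082), where it did not pass either. Asns, with the smallest p there, differed by -0.19 ± 0.08.

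Goblet cell and mucus genes were higher at high calcium. Tff3, a trefoil peptide secreted with mucus, differed by 0.29 ± 0.09, and Muc2, the main gel-forming mucin of the colon, by 0.23 ± 0.07. These 2 passed adjusted over the list alone; Tff1 (0.25 ± 0.09) and Clca1 (0.45 ± 0.18), both goblet cell products, did not. Of 19 measured members 16 were higher, and 0 passed over all genes. The list mean was 0.06 ± 0.11 (SD, n = 8) at high and -0.12 ± 0.08 (SD, n = 9) at low calcium, and all 8 high calcium rats lay above the low calcium mean. The rise passed camera (adjusted p = 7.50e-05), camera with an estimated correlation (adjusted p = 0.037) and the exact permutation test (adjusted p = 0.022). The count of 2 members was 0 without rat 1, 2, 4, 10, 11, 13, 16, 17 or 18, 1 without rat 6, 9 or 15, and 7 without rat 3. It was 0 with the slide as a block, median centring, a normexp offset of 0, the scanner software's processed signals or the smooth muscle covariate. With the Cy5 channel alone it was 1, and with array weights 8. The list median was 0.20 with the slide as a block and 0.26 with median centring, against 0.20 as reported.

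Enteroendocrine, absorptive and oxidative phosphorylation genes passed camera as higher, by small amounts. Enteroendocrine markers had a median of 0.06 with 14 of 18 members higher (camera adjusted p = 0.029, adjusted p = 0.31 with an estimated correlation). The hormone genes Ghrl (0.27 ± 0.09), Sst (0.28 ± 0.10) and Pyy (0.16 ± 0.06) had the smallest p. Absorptive and electrolyte transport genes had a median of 0.08 (camera adjusted p = 0.035, adjusted p = 0.47 with an estimated correlation). The members with the smallest p went both ways, with uroguanylin (Guca2b) at -0.46 ± 0.15 and the water channel Aqp3 at 0.37 ± 0.15. Oxidative phosphorylation genes had a median of 0.03 (camera adjusted p = 0.035, adjusted p = 0.66 with an estimated correlation), with Cox8a at 0.12 ± 0.05. In these lists 0 members passed adjusted over the list alone. The enteroendocrine count was 1 without rat 3, 2 without rat 13 and 6 with no background correction, and the absorptive count was 1 without rat 5 or rat 18. They were called in 27, 21 and 17 of 32 camera settings, in the order given, and with the slide as a block the oxidative phosphorylation list did not pass (median 0.03, camera adjusted p = 0.088).

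Epithelial and calcium-related lists did not pass as analysed, although the epithelial identity list was called in 7 and the junction list in 4 of 32 other camera settings. Epithelial identity genes had a median of 0.06 (camera adjusted p = 0.078); a single member passed adjusted over the list alone, the keratin Krt7, at -0.58 ± 0.12, and 0 passed with median centring. Tight and adherens junction genes had a median of 0.03 (camera adjusted p = 0.18). Their 5 members with the smallest p went both ways: Pkp2 (0.13 ± 0.04), Cldn12 (0.15 ± 0.06) and Crb3 were higher, Gja1 and Cldn5 lower. Calcium handling and vitamin D response genes had a median of 0.03 (camera adjusted p = 0.84). That median was -0.0037 with the slide as a block and also without rat 1, which was alone on its slide. Of 19 members 0 passed adjusted over the list alone, or 1 with the scanner software's processed signals. Trpv6, the calcium channel of the absorbing epithelium, differed by -0.36 ± 0.13 and the vitamin D receptor Vdr by 0.11 ± 0.07. Antimicrobial defence genes had a median of 0.05 (camera adjusted p = 0.86), with lysozyme (Lyz2, -0.64 ± 0.14) as the single member past adjusted over the list alone; 2 passed without rat 3 or with array weights, and 0 with median centring. Mast cell and eosinophil markers had a median of -0.01 (camera adjusted p = 0.79) whose sign turned in 18 other settings, and the eosinophil granule gene Prg2, at 0.28 ± 0.08, was the single member past. There 0 passed with the slide as a block, with median centring, or without rat 1, 2, 4, 5, 7, 8, 10, 13, 14, 16 or 18.

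**Figure D2:**
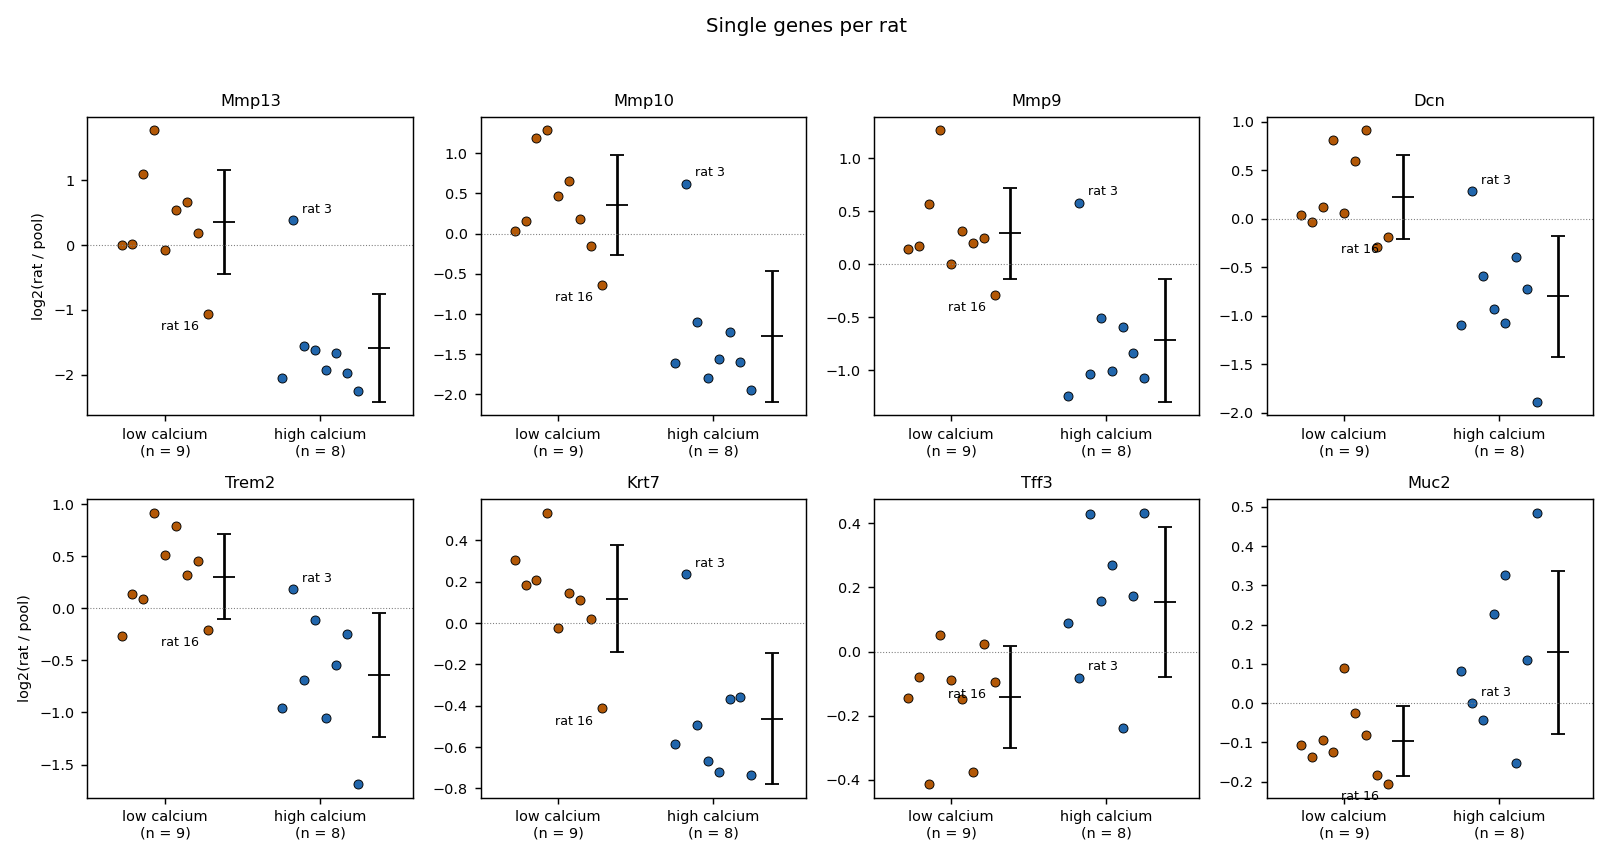
Log2 ratio to the common pool (vertical axes) of 8 single genes, 1 point per rat, for 9 low and 8 high calcium rats; bars give the mean ± SD of each group. Mmp13 averages -1.58 at high and 0.35 at low calcium, with rat 3 at 0.39, and Muc2 averages 0.13 and -0.10.

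Single genes were tested over 27101 probes for 23176 gene names. With limma, 0 probes and 0 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2382 probes, of which 1070 were higher and 1312 lower, where chance alone would give 1355 on average. This count was 780 with median centring, 1389 with the smooth muscle covariate and 3790 with array weights. The balance of directions turned with the series matrix values (1272 higher, 1089 lower) and without rat 8 (1139 higher, 1087 lower). At an unadjusted p under 0.001 there were 136 probes, 124 of them lower, against 27 by chance on average. Counts by chance can lie far from such averages. Other splits of the rats gave up to 4054 probes at an unadjusted p under 0.05, and 11 of 100 splits, the real one included, gave at least 2382. The count under 0.001 was not set against the splits. The smallest adjusted p was 0.098. Among the lower genes with the smallest p that are not given above were Nppb, a natriuretic peptide (-1.17 ± 0.21), and the chemokine Cxcl14 (-0.37 ± 0.07). The higher genes with the smallest p were Gbe1 (0.21 ± 0.04), Rab27b (0.24 ± 0.05), Olr193 (0.16 ± 0.04), Epas1 (0.24 ± 0.06) and Rab3b (0.36 ± 0.09), with adjusted p from 0.13 to 0.19. The 2 probes of Gbe1 differed in sign, and Olr193 had the opposite sign when the rat's channel was used alone. Of the 33 gene lists 14 passed camera, 10 lower and 4 higher; 3 passed with an estimated correlation, 4 passed fry, and 5 passed the exact permutation test after adjustment. Of 100 splits of the 17 rats into groups of 8 and 9, the real one included, 17 gave 14 or more lists by camera. The other splits gave a median of 8 lists, and 94 of them called at least 1. A pass by camera at the preset correlation alone therefore carries little weight, however small its p.

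High calcium rat 3 and low calcium rat 16, which shared a slide, stood apart from their groups. The protease list mean was 0.19 in rat 3 and -0.16 in rat 16, and the matrix list mean was 0.21 and -0.07. Slides 1 to 4 each held 2 rats of either diet, and the protease difference within them was -0.06, -0.54, -0.51 and -0.59, with the smallest on the slide of these animals. For the matrix list the differences were -0.02, -0.43, -0.49 and -0.48, and for the goblet list 0.17, 0.21, 0.09 and 0.26. Slide 5 held low calcium rat 1 alone. A slide block therefore takes that rat out of the difference and, apart from missing values, changes the estimate in no other way. With the slide as a block the differences of the list means were -0.43 ± 0.10, -0.36 ± 0.09 and 0.18 ± 0.05 (SE) for proteases, matrix and goblet genes, and 0 probes passed. Without rat 3 limma called 193 probes, 16 higher and 177 lower, for 165 genes; without rat 16 it called 38 probes, all lower, for 33 genes. Leaving out any other single rat gave 0.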

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

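The muscle covariate was planned for the counts, lists and genes, but its use on list means as a test of the fall, the tests of other cell types and those of the diet score were chosen after the results they bear on had been seen, as were the splits balanced over slides. The test of the reference channel and the free splits of the rats were set beforehand. Groups were searched for a highest or lowest rat far from the others in 20 list means and 100 named genes. Of 240 groups 12 had such a rat, and chance would give about 12. The high calcium group of Pyy is counted among the 240 but was not searched, because a value is missing there. Rat 3 accounted for 6 of the 12, always as the highest high calcium rat.

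In high calcium rat 3 the protease list mean was 0.19, against -0.23 in the next rat, and the unfolded protein response mean was 0.26 against 0.03. Its log2 ratios to the pool were 0.39 for Mmp13 (next rat -1.56), 0.62 for Mmp10 (-1.10), 0.58 for Mmp9 (-0.51) and 0.24 for Krt7 (-0.36). Low calcium rat 16 stood out on the same side as the high calcium rats on the protease list, at -0.16. To place them, the 200 probes with the smallest p were taken from a fit without either rat, on a scale where 0 is the low and 1 the high calcium mean, and each other rat was scored with itself left out too. Rat 3 scored -0.045, within the other low calcium rats (-0.52 to 0.37). Rat 16 scored 0.70, within the other high calcium rats (0.55 to 1.63).

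An exchange of the 2 samples needs both of these positions and both were found, so it stays open. Correct labels on 2 rats whose inflammation differs from that of their groups predict the same positions. The score cannot tell these apart. A wrong label on rat 3 alone cannot be told apart from an individual rat with strong inflammation, since both predict its score of -0.045. Some named genes go the other way. They were picked with rat 3 counted as high and rat 16 as low calcium, which favours genes where both keep to their labels. On 7 of 100 named genes, among them Trpv6 (-0.91), Guca2b (-1.02) and Rab27b (0.35), rat 3 lay beyond every low calcium rat on the high calcium side, and on 11 rat 16 lay beyond every high calcium rat on the low side. The 7 genes of rat 3 do not exclude an exchange: each low calcium rat, set against the others, gave 1 to 32 such genes, and other high calcium rats 27 to 84. No such range stands beside the 11 genes of rat 16, so no conclusion is drawn from them. Of the 200 probes of the score rat 3 lay beyond the low calcium rats on 13, against 3 to 115 for these rats themselves. Rat 16 lay beyond the high calcium rats, on the low side, on 40, against 2 to 119 for these. Set against its own group, rat 3 lay beyond every other high calcium rat on 186 and rat 16 beyond every other low calcium rat on 147. The probes of the score are nearly all lower at high calcium. A score from higher probes alone put rat 3 at -0.20 but did not part the groups (low -0.17 to 0.68, high -0.14 to 1.54). The labels were kept as given throughout, apart from the splits of the rats described below. No comparison was made with these 2 rats alone reassigned.

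The second pattern is the joint fall of the matrix, fibroblast and protease lists. Less smooth muscle in the high calcium scrapings was examined with the smooth muscle mean as a covariate. The matrix difference was then -0.24 ± 0.06 (SE), still beyond 2 SE, against -0.35 ± 0.09 without it. The fibroblast difference went from -0.34 ± 0.10 to -0.20 ± 0.05 and the protease difference from -0.42 ± 0.09 to -0.33 ± 0.08. The smooth muscle list is an imprecise measure of muscle, with 10 of its 17 members lower and 7 higher. A remainder after this covariate is thus possible even if muscle were the whole cause. Muscle as a part or the whole of the cause stays open. A larger epithelial share lowering all other cell types alike would move the non-epithelial lists together. The fibroblast list fell by 0.32 more than the mean of the T and NK, B and plasma, and enteric neuron and glia lists (exact permutation p = 0.0044). Those 3 list means differed by -0.010, -0.060 and 0.026 in the order given, and their joint mean by -0.015. None of the 3 passed camera. Against all 8 other non-epithelial cell type lists, with the macrophage, neutrophil, endothelial, smooth muscle and mast cell lists among them, the fibroblast list fell by 0.25 more (exact permutation p = 0.0059). The fibroblast list and the lists set against it were chosen after their values were seen, so these p-values partly restate that choice. They speak at most against a fall alike in all cell types, and a lower share of only some of them was not tested. Array effects on these probes are argued against by the reference channel, the same RNA on every array, in which the matrix difference was 0.0047 ± 0.0064, against -0.39 ± 0.10 in the rat's channel alone. Dietary calcium is the factor by which the groups differ, and the exact permutation tests in the report compared them as labelled. Calcium as the cause of the fall stays open, and the doubt about rats 3 and 16 applies to it.

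The third concerns the counts. In 100 splits of the 17 rats, the real one included, 17 gave at least the 14 lists that passed camera (highest other 22), and 11 gave at least the 2382 probes at an unadjusted p under 0.05 (highest other 4054). Chance is therefore not excluded for these counts. In 100 splits of the 1296 that keep 2 rats of either label on slides 1 to 4, as the real one does, 31 gave at least 14 lists (highest other 23) and 12 at least 2382 probes (highest other 3956). All 100 free splits gave at least the real 0 probes and 0 genes past the threshold, and the highest other was 0 for both. All 100 balanced splits did so too, and 2 of the others called any: the highest gave 289 probes and 255 genes, with high calcium rats 3 and 14 and low calcium rats 7 and 16 in the opposite group. That split holds the pair whose labels are in doubt, and no further structure was tested. The exact permutation tests of single lists in the report are separate from these counts.

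Of the remaining values, low calcium rat 15 was lowest in its group for Madcam1 (-0.35), Ccl7 (-0.58) and Cald1 (-0.43). Low calcium rat 6 was lowest for Ghrl (-0.56) and Sst (-0.55). High calcium rat 14 was highest for Tgfb1 (0.093).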

How the results depend on the processing

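Leaving out rats 3 and 16 together, and the counts of members past adjusted over the list alone, and of probes at an unadjusted p under 0.05, under other settings, were chosen after seeing the data; all other settings were planned. No probe or gene passed under any alternative that kept all 17 rats. Without 1 rat at a time the count ran from 0 to 193 probes and from 0 to 165 genes, with 38 probes and 33 genes without low calcium rat 16 and the highest without high calcium rat 3. Without both rats it was 328 probes and 289 genes, but they were picked for lying against their groups, which raises the count by construction. In that setting 13 protease, 22 matrix and 7 goblet genes passed adjusted over the list alone. The 14 lists became 3 in camera with an estimated correlation, 4 in fry and 5 in the exact permutation test; the last pair also test against no change, not against other genes, so their counts differ from 14 in more than the correlation. Other camera settings gave 10 to 19 lists. Of the 14 lists 10 were called in each of the 32 camera settings, with medians of -0.38 to -0.16 for proteases, -0.45 to -0.20 for matrix structure, -0.44 to -0.20 for fibroblast, -0.24 to -0.094 for macrophage, -0.36 to -0.070 for neutrophil, -0.20 to -0.058 for complement, -0.24 to -0.043 for endothelial, -0.17 to -0.045 for cytokine, -0.15 to -0.051 for inhibitor and 0.11 to 0.26 for goblet genes. Over 14 other settings with all rats the members past adjusted over the list alone ran from 0 to 23 for matrix structure (20 as reported), 0 to 13 for fibroblast (12), 6 to 13 for protease (12), 0 to 13 for macrophage (11), 0 to 9 for complement (9), 2 to 7 for neutrophil (6), 0 to 8 for endothelial (3), 0 to 4 for inhibitor (4) and 0 to 8 for goblet genes (2). The lowest of these came with median centring, in some lists with other settings too; it leaves in the dye bias that depends on intensity and raised the median residual SD from 0.12 to 0.27. Leaving out 1 rat gave 18 to 22 matrix, 10 to 13 fibroblast, 12 to 13 protease and 10 to 12 macrophage genes. Signs reversed for Olr193 in the Cy5 channel alone (-0.14), Gata2 in the series matrix (0.020), and Kit on averaging its probes (-0.0027), which differ in sign. Of the 14 lists that passed, the median of 1 reversed, the unfolded protein response, with median centring (0.0011) and the smooth muscle covariate (0.0082). Of the other 19 lists, with medians near 0, 11 reversed under some setting. With no background correction the medians were -0.0024 for B and plasma, -0.0071 for oxidative stress, 0.019 for immediate early and 0.028 for mast cell genes, and with the scanner software's processed signals -0.0059, -0.0094, 0.028 and 0.040. Median centring gave -0.012 for enteric neuron, 0.019 for T and NK, 0.032 for immediate early, 0.060 for proliferation and 0.080 for mast cell genes. The Cy5 channel alone gave -0.024 for B and plasma, -0.016 for oxidative stress, -0.00023 for enteric neuron, 0.023 for immediate early, 0.00030 for proliferation, 0.051 for mast cell and -0.011 for calcium handling genes. The series matrix gave 0.038 for immediate early, 0.016 for proliferation and 0.050 for mast cell genes. No filter gave -0.0010 for B and plasma and -0.013 for calcium handling genes, and the strict filter -0.015 for B and plasma and 0.016 for mast cell genes. The slide as a block gave -0.0037 for calcium handling, the same value as without rat 1, which that block takes out of the difference. Array weights gave -0.00076 for calcium handling, 0.027 for immediate early and 0.027 for mast cell genes. The smooth muscle covariate gave -0.018 for B and plasma, -0.0056 for cholesterol, 0.013 for immediate early, 0.0026 for proliferation and 0.049 for mast cell genes. Without rats 3 and 16 the medians were -0.015 for B and plasma, -0.012 for interferon, -0.0054 for antigen presentation and 0.040 for mast cell genes. Leaving out 1 rat gave medians from -0.043 to 0.022 for B and plasma, -0.013 to 0.022 for oxidative stress, -0.015 to 0.064 for interferon, -0.0062 to 0.030 for antigen presentation, -0.024 to 0.017 for immediate early, -0.044 to 0.015 for proliferation, -0.056 to 0.058 for mast cell and -0.0051 to 0.041 for calcium handling genes. Apart from that under the slide block, which amounts to leaving out rat 1, the cause of these reversals was not tested. Of 3230 values of named genes 3149 kept their direction and side of the threshold and 78 newly passed. Of 490 values of the 14 lists 425 did and 63 lost the call; of 664 values of the other 19 lists 542 did, 39 newly passed and 83 reversed. Loess followed by Aquantile leaves the ratios untouched and so tests nothing, and scan date as a block was not run because all arrays share 1 date. No paired analysis was possible because no replicate number occurs in both groups. Signal over background limits dim genes: Stc1 was well above background on 2 of 8 high and 6 of 9 low calcium arrays.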

Other observations

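The camera and exact permutation tests of the lists were planned, while the relations within a diet were chosen after list means had been seen. The lists not described in the report did not pass camera as analysed. In other camera settings fatty acid oxidation and PPAR targets were called in 12 of 32, proliferation and interferon-stimulated genes in 2 each, and cholesterol synthesis and oxidative stress genes in 1 each, the last as lower in the Cy5 channel alone (adjusted p = 0.035). T and NK cell markers had a median difference of -0.02 (camera adjusted p = 0.31), B and plasma cell markers 0.0004 (adjusted p = 0.24), interferon-stimulated genes 0.02 (adjusted p = 0.41), antigen presentation genes 0.01 (adjusted p = 0.67) and proliferation genes -0.01 (adjusted p = 0.68). Enteric neuron and glia markers had 0.03 (adjusted p = 0.31), immediate early genes -0.003 (adjusted p = 0.67), fat and pancreas markers 0.02 (adjusted p = 0.78) and circadian clock genes 0.05 (adjusted p = 0.92). Cholesterol synthesis had 0.02 (adjusted p = 0.27), bile acid, nuclear receptor and transporter genes 0.06 (adjusted p = 0.29), and fatty acid oxidation and PPAR targets 0.05 (adjusted p = 0.056). The signs of the B and plasma, T and NK, interferon, antigen presentation, proliferation, enteric neuron, immediate early and cholesterol medians turned under some settings.

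Oxidative stress and xenobiotic genes had a median of 0.01 (camera adjusted p = 0.28), while 4 of 37 members passed adjusted over the list alone, all lower. Chosen after their values were seen, these were the glutathione transferases Gsta1 (-0.50 ± 0.10) and Gsta2 (-0.41 ± 0.12), the aldo-keto reductase Akr1b8 (-0.37 ± 0.09) and the glutathione peroxidase Gpx3 (-0.22 ± 0.07). This count was 2 without rat 1, 11 or 18 and with the slide as a block, 1 with the smooth muscle covariate and 0 with median centring. The median and the mean of that list differ in sign, and its mean per rat gave an exact permutation p of 0.019, which did not pass after adjustment (0.064). In other lists, likewise seen first, Fabp4 (-0.53 ± 0.13), the clock gene Bhlhe41 (-0.57 ± 0.13) and the lysosomal protease Ctss (0.17 ± 0.05) passed adjusted over their list alone. With median centring 0 passed in each of these lists, and the antigen presentation count, Ctss alone, was also 0 when any single one of 11 rats was left out and in 6 other settings, the slide as a block among them. For the fat and pancreas list, with Fabp4 alone, it was 0 with the smooth muscle covariate too.

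Within each diet, list means were related across rats, 6 relations in all, leaving members of the protease list out of the other list. Macrophage markers rose with protease genes in both groups. In the 9 low calcium rats r was 0.74 (permutation p = 0.031, adjusted 0.061) and rho 0.85 (permutation p = 0.0061, adjusted 0.018); in the 8 high calcium rats r was 0.76 (permutation p = 0.044, adjusted 0.066) and rho 0.98 (permutation p = 0.00040, adjusted 0.0024). Without the 2 rats farthest from the median r was 0.71 and 0.77. Neutrophil markers gave r of 0.82 (permutation p = 0.0093, adjusted 0.028; rho 0.57, permutation p = 0.12, adjusted 0.16) and 0.86 (permutation p = 0.0032, adjusted 0.019; rho 0.76, permutation p = 0.037, adjusted 0.074). Those fell to 0.18 and 0.60 without the 2 farthest rats, so the low calcium relation rests on them. Each slide held at most 2 rats of a diet, too few for a value within slides.

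One hypothesis was that mucus genes are lower in rats of the same diet whose protease genes are higher. The goblet list gave r of -0.42 at low calcium (permutation p = 0.26, adjusted 0.26; rho -0.32, permutation p = 0.41, adjusted 0.41) and -0.68 at high calcium (permutation p = 0.061, adjusted 0.073; rho -0.60, permutation p = 0.13, adjusted 0.16). Without the 2 farthest rats these became 0.51 and -0.27, so neither relation held and the hypothesis stays undecided.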
